A study of Cereibacter sphaeroides 2.4.1 with 8 samples.

How the data were processed

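RNA of 8 cultures or samples of Rhodobacter sphaeroides was measured on 1-colour Affymetrix arrays after biotin labelling, per the labels' protocols. The labels give 3 groups: molybdenum (3 arrays), tungsten in place of molybdenum (3 arrays) and tungsten plus molybdenum (2 arrays), all under light of 10 W/m2. The deposited value table holds 1 linear intensity per probe set and array, as whole numbers. RMA and MAS5 are named per the submitters' processing notes; which of them made the values, in what order, in which version, and whether the arrays were normalized together is not given in the sources used here. No scanner files or detection calls were used here, so no probe set could be called present or absent. The median intensity per array lay between 111 and 123 and the lowest value between 19 and 20. On the log2 scale the medians spanned 0.16, under the limit of 0.2 above which quantile normalization would have been applied, so the intensities were used as deposited, with values under 1 set to 1 (there were none) before log2. The quartiles differed more: molybdenum replicates B and C had upper quartiles of 8.32 and 8.34, and the other arrays 8.59 to 8.72.

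The array annotation gives a single gene symbol to 542 of 5355 probe sets, several symbols to 0 and none to 4813. A probe set without a symbol is unnamed here, not without a gene. The 3 probe sets for the spiked-in control thrC (intensities 20 to 33) were left out, which leaves 5352 tested probe sets, 539 of them with a symbol. These stand for 498 symbols, of which 494 also occur in the reference annotation ASM332471v1; none of its gene identifiers matched, and no coordinates were taken from it. Probe sets of 1 gene were tested separately. The symbols moaA, sdhA, atpA, atpD and fumC, each shared by different gene identifiers, are given with the probe set number.

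limma 3.58.1 in R 4.3.3 fitted log2 intensity by group over all 8 arrays (lmFit, contrasts.fit, eBayes), so that the groups share 1 estimate of the spread with 5 residual degrees of freedom. All 3 pairwise comparisons were tested, two-sided, with Benjamini-Hochberg adjustment over the 5352 probe sets and a threshold of 0.05. Adjusted p-values, log2 differences and standard errors come from this fit unless an alternative is named. SDs are those of the arrays of a group.

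Before the data were examined, 26 gene lists were written from the biology of the organism and of molybdenum, with members found by the gene symbol. Of these, 20 had at least 3 measured members and were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the lists within a comparison; camera with an estimated correlation and fry were run as alternatives. The tested lists were molybdenum transport and cofactor synthesis, molybdoenzymes, nitrogenase and rnf, photosynthetic complexes, bacteriochlorophyll and carotenoid synthesis (called pigment synthesis for short), haem and tetrapyrrole synthesis, cobalamin synthesis, hydrogenase, terminal oxidases and cytochromes, NADH dehydrogenase, ATP synthase, ribosomal proteins, flagella and chemotaxis, chaperones and proteases, oxidative stress, iron uptake and storage, sulphur uptake and assimilation, phosphate and phosphonate uptake, nitrogen assimilation and the tricarboxylic acid cycle. The lists Calvin cycle (2 members), other metal transport (2), iron-sulphur cluster assembly (1) and polyhydroxyalkanoate storage (1) were too small, and denitrification and mobile elements had 0 members. Matching respected case, so HemH, SufC and ArsH fell in no list; hemT lies in both the haem and the iron list and cbiQ in both the cobalamin and the other metal list. Within each list, genes were also counted after adjustment over the list alone. For the lists called in any comparison below, the estimated correlation ran from 0.17 (terminal oxidases and cytochromes) to 0.95 (photosynthetic complexes). As these values exceed the preset, camera's p-values at the preset overstate the evidence for the called lists.

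The rule for the genes named was fixed at the same time: for each comparison the 12 largest rises and 12 largest falls past the threshold without overlap between the groups or, where none pass, the 10 probe sets with the smallest p, and up to 4 members with the smallest p from each list camera called and from 5 lists always named (molybdenum transport and cofactor synthesis, molybdoenzymes, nitrogenase and rnf, photosynthetic complexes, bacteriochlorophyll and carotenoid synthesis). Since 0 probe sets passed in each comparison, the 10 smallest p applied. Probe sets without a symbol are given by number for the clearest few and otherwise counted. Genes named outside the rule are said to have been chosen after their values were seen; cbbX and the cobalamin genes cobA and cobN are among these.

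The alternatives were quantile normalization, median centring, leaving out the 25% dimmest probe sets, only the 2 groups compared, an intensity trend or robust estimation in eBayes, a 2-fold minimum, the replicate letter as a block, array weights, an offset of 16 before log2 and leaving out each array in turn. After seeing the data, 2 were added: leaving out both replicates A of the groups with molybdenum, and 1 value per gene in the list tests. The limma fit and the set test were tried on simulated data with the real means, in which each probe set varied independently. Each had 1 spread, that of the fit, on all 8 arrays. The real spread was uneven: the gene pufM had an SD of 1.43 over the molybdenum arrays and 0.10 over the tungsten arrays. The shares recovered therefore do not tell how many real changes these arrays could detect. In the comparison of tungsten with molybdenum, limma recovered 64.2% of 67 probe sets changed 2-fold, 86.6% of 67 changed 4-fold and 89.4% of 66 changed 8-fold, and called 0.155% of 5152 unchanged ones; in tungsten plus molybdenum against molybdenum the shares were 43.3%, 77.6% and 95.5%. In tungsten against tungsten plus molybdenum they were 43.3%, 77.6% and 89.4%. The set test called the 1 list moved and 0 others. As each probe set varied independently, this could not show false calls of lists whose members vary together. Figures were drawn with matplotlib 3.10.9.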

Results

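Rhodobacter sphaeroides is a purple bacterium that can live by photosynthesis without oxygen. RNA from cells kept in closed vessels under light of 10 W/m2 was hybridised to 8 Affymetrix arrays, which give 1 fluorescence intensity per probe set, a group of probes for 1 transcript. The cells had grown with molybdenum, the metal of the normal medium (3 arrays, replicates A, B and C), with tungsten in its place (3 arrays, replicates A, B and C) or with both metals (2 arrays, replicates A and B). Tungstate resembles molybdate chemically and is widely used as its antagonist, because enzymes that carry tungsten in the molybdenum cofactor are mostly inactive. The title of the series names the transcriptional response to tungsten as its subject. Values are log2 intensities, given as mean ± SD over the arrays of a group. No label says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

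Molybdenum replicate B stood apart from the other 7 arrays. Its log2 intensities correlated with theirs at r = 0.831 to 0.861 across probe sets, while the remaining pairs lay between 0.937 and 0.997. Probe sets are not independent replicates. On that array all 11 probe sets of the photosynthetic complexes and 25 of 26 of bacteriochlorophyll and carotenoid synthesis read below the other 7 arrays, as did 22 of 23 of flagella and chemotaxis, 38 of 45 of ribosomal proteins, all 5 of hydrogenase and 8 of 11 of cobalamin synthesis. Over all 5352 probe sets 1676 read below them and 1693 above. For example pufM, which encodes a reaction centre subunit, read 10.16 there against 12.93 and 12.16 in molybdenum replicates A and C. Of the 7 oxidative stress genes 5 read above the other 7 arrays and 2 below. Among them trxA, which encodes thioredoxin, gave an intensity of 2233 against 435 and 598, and chrR, which encodes the anti-sigma factor of the singlet oxygen response, 1381 against 325 and 267, while gor, for glutathione reductase, gave 178 against 414 and 233. The genes trxA, chrR and gor and these counts were chosen after the values were seen. The closest pair of all was molybdenum replicate A and tungsten plus molybdenum replicate A (r = 0.997), closer than the nearest replicates of 1 group, tungsten A and B (r = 0.990).

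**Figure D1:**
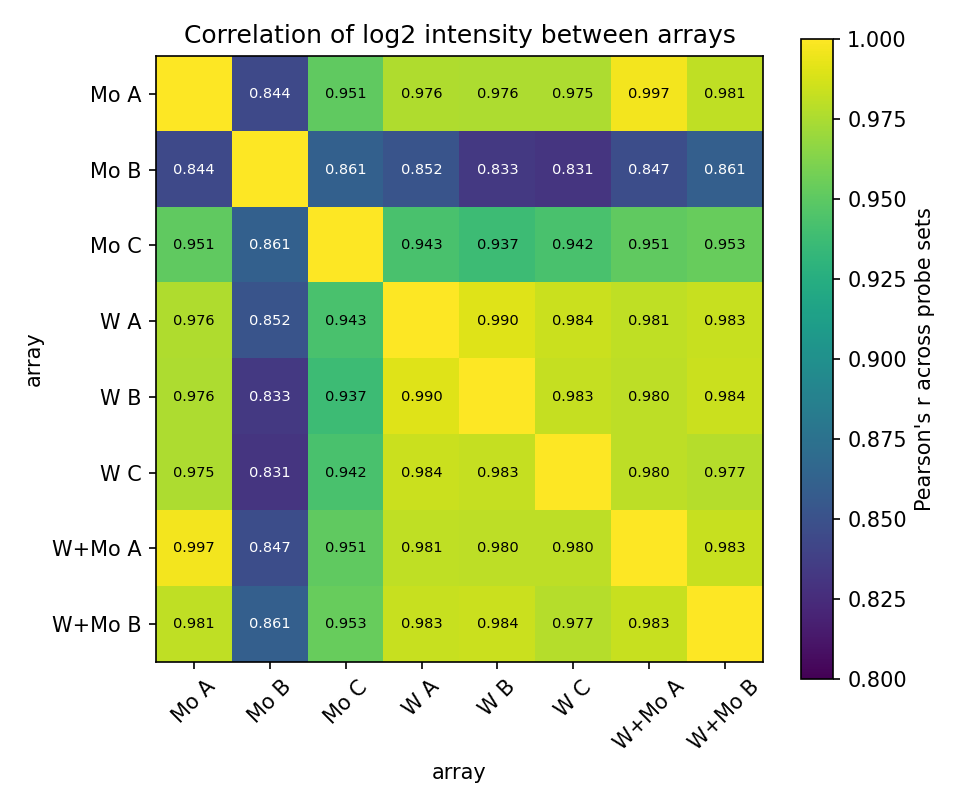
Pearson correlation of log2 intensity across probe sets for each pair of the 8 arrays (Mo, molybdenum; W, tungsten in place of molybdenum; W+Mo, both metals; letters are replicates). Molybdenum replicate B has no value above 0.861, and the highest value, 0.997, joins replicates A of the groups Mo and W+Mo.

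The comparison of tungsten in place of molybdenum with molybdenum asks what changes when tungsten replaces the metal. The gene cbbX, whose product is the activase of the carbon-fixing enzyme Rubisco, was 9.68-fold higher with tungsten, at 11.15 ± 0.45 (n = 3) against 7.87 ± 1.36 (n = 3), a log2 difference of 3.28 (SE 0.73); without molybdenum replicate B it was 2.49 and without A 3.72. All 11 probe sets for cobalamin (vitamin B12) synthesis were higher with tungsten, by a median of 1.30, as were all 11 for the photosynthetic complexes (median 1.42). All 26 in the list of bacteriochlorophyll and carotenoid synthesis, which includes regulators, were higher as well (median 1.08). The gene moaA, whose product starts the synthesis of the molybdenum cofactor, was lower: probe set 3999 read 8.39 ± 0.41 (n = 3) with tungsten and 10.15 ± 0.76 (n = 3) with molybdenum, a log2 difference of -1.75 (SE 0.42). None of these genes passed limma's test over all 5352 probe sets: 0 were called, the lowest adjusted p being 0.141, and 601 had an unadjusted p under 0.05 (426 higher, 175 lower) where 268 would be expected by chance. Without molybdenum replicate A limma called 395, 269 of them higher, and without replicate B 1. It called 1379 with array weights and 1 with an intensity trend. The weights were 0.252 for molybdenum replicate A, 0.114 for B and 2.16 for C, so the weighted molybdenum mean rests mainly on replicate C.

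Among the 8 probe sets for molybdenum transport and cofactor synthesis, 2 passed when adjusted over the list alone and 0 over all genes. They were moaA (probe set 3999; adjusted p = 0.0151 over the list alone) and mobB, which encodes a protein of the final steps of cofactor assembly and was higher with tungsten by 0.78 (SE 0.17; adjusted p = 0.0151 over the list alone). Without molybdenum replicate C or tungsten replicate C 0 passed, without tungsten replicate B 1, and without molybdenum replicate A 3. The gene modA, for the binding protein of the molybdate transporter, read 8.25 ± 0.52 (n = 3) with tungsten and 7.28 ± 0.80 (n = 3) with molybdenum, and mobA 7.92 ± 0.41 and 7.53 ± 0.34. The list as a whole was not called (limma's camera, adjusted p = 0.535). Its median was 0.19 and its mean -0.05. Of the 4 genes in the molybdoenzyme list, none of which is for dimethyl sulphoxide reductase itself, 0 passed over the list alone. The log2 difference was 0.39 (SE 0.16) for dorS and -0.34 (SE 0.20) for dorR, the sensor and regulator genes of that reductase. It was 0.41 (SE 0.30) for xdhA of xanthine dehydrogenase and -0.01 (SE 0.25) for xdhC. Without molybdenum replicate B, dorS (0.47) and dorR (-0.53) both passed over the list alone.

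Nitrogenase, whose usual form carries molybdenum, was represented by 11 nif genes. Only nifA, the activator of the nif genes, passed when adjusted over the list alone, with 7.73 ± 0.08 (n = 3) against 7.07 ± 0.22 (n = 3), and 0 passed over all genes. It no longer passed without molybdenum replicate C or without any 1 array of the groups with tungsten. Without molybdenum replicate A 5 passed, nifA and the lower nifH, nifD, nifE and nifN. The structural gene nifD read 5.54 ± 0.08 (n = 3) and 5.85 ± 0.24 (n = 3), near the bottom of the scale, nifN 4.95 ± 0.05 and 5.20 ± 0.18, and nifB 5.34 ± 0.08 and 5.55 ± 0.25. The list was not called (camera, adjusted p = 0.220).

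Photosynthesis genes were higher with tungsten in every measured member. The list of photosynthetic complexes, 11 probe sets of 7 genes, was called by camera (adjusted p = 0.000106), as were bacteriochlorophyll and carotenoid synthesis, 26 probe sets of 18 genes (adjusted p = 1.92e-09). The estimated correlation between members was 0.95 for the complexes and 0.89 for pigment synthesis, far above the preset. The p-values at the preset therefore overstate the evidence. With the estimated correlation each list had an adjusted p = 0.555. The pigment list also holds the regulator gene tspO and ppsR, for the repressor of photosynthesis genes, the latter with 5 probe sets. The genes pufM and pufL, for the reaction centre subunits, differed by 1.59 (SE 0.63) and 1.62 (SE 0.65), pufX by 1.52 (SE 0.63) and pucC, for assembly of the peripheral antenna, by 1.56 (SE 0.53). In pigment synthesis, bchI, for a magnesium chelatase subunit, differed by 1.64 (SE 0.56), the regulator tspO by 1.62 (SE 0.52), bchO by 1.16 (SE 0.27) and bchE, for the oxygen-independent cyclase, by 0.81 (SE 0.22). These groups moved with molybdenum replicate B: without it the median fell to 0.59 in the complexes and 0.43 in pigment synthesis. Adjusted over the list alone 0 of 11 and 0 of 26 passed, as over all genes. Without molybdenum replicate B 6 and 6 did, and without molybdenum replicate A 6 and 24.

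Cobalamin synthesis was called by camera (adjusted p = 6.5e-05; adjusted p = 0.555 with an estimated correlation). Adjusted over the list alone 6 of its 11 genes rose, cobA, cobF, cobM, cobN, cobW and cbiQ, and 0 over all genes. Without any 1 tungsten array 0 passed. The gene cobW stood at 11.50 ± 0.15 (n = 3) against 10.14 ± 0.79 (n = 3), and cobM at 9.78 ± 0.15 against 8.34 ± 0.86. The gene cobF stood at 9.02 ± 0.19 against 7.72 ± 0.85, and cbiQ, of a cobalt transporter, at 8.24 ± 0.39 against 6.96 ± 0.57. The list's median was 0.81 without molybdenum replicate B, in which cobW read 9.23 against 10.54 and 10.66.

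Phosphate uptake was also called (camera, adjusted p = 0.0191; adjusted p = 0.555 with an estimated correlation), though not without molybdenum replicate A (adjusted p = 0.0592) or C (adjusted p = 0.0555). Its 3 transporter genes pstA (1.04, SE 0.27), pstC (1.01, SE 0.34) and pstB (0.76, SE 0.26) passed when adjusted over the list alone, and 0 of 5 over all genes. The regulator gene phoU differed by 0.19 (SE 0.27). Over the list alone 0 passed without molybdenum replicate B or C, tungsten replicate A, or either array with both metals. Flagella and chemotaxis were called too (median 0.82; adjusted p = 0.00219; adjusted p = 0.773 with an estimated correlation), with 0 of 23 past the test over the list alone or over all genes. Among them fliP differed by 1.43 (SE 0.58), flhB by 0.82 (SE 0.32), fliQ by 0.87 (SE 0.41) and flgA by 0.74 (SE 0.35). The call was lost without molybdenum replicate B (median 0.14, adjusted p = 0.492) or tungsten replicate B (adjusted p = 0.0624).

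In other lists the following genes passed over the list alone, and none over all genes; they were chosen after their values were seen. Of 8 probe sets of the tricarboxylic acid cycle 5 passed: sdhA of succinate dehydrogenase (probe set 1875, 1.19, SE 0.21), sucD (0.98, SE 0.19) and sucC (0.74, SE 0.25) of succinyl-CoA synthetase and gltA of citrate synthase (0.50, SE 0.16) were higher. The dim probe set 4098, also named sdhA, was lower (-0.37, SE 0.12). Without molybdenum replicate B or C or tungsten replicate A or B 2 passed, and without tungsten replicate C 3. The gene cbbX passed limma's test over its list of 2 (adjusted p = 0.00531), also without any 1 of the molybdenum or tungsten arrays. That list was too small for the list tests. An adjustment over 2 probe sets does not allow for the choice of cbbX after its values were seen. The repeats share most arrays and are not independent. The other gene in the list, cbbR, which encodes the regulator of the Calvin cycle genes, read 6.59 ± 0.10 (n = 3) and 6.49 ± 0.41 (n = 3). In haem synthesis hemN (0.97, SE 0.23) and hemB (0.73, SE 0.22) passed among 7. Neither did without molybdenum replicate B or C or any 1 tungsten array, and 1 did without either array with both metals. In iron uptake feoB, for the ferrous iron transporter, passed among 6 (0.78, SE 0.21), and did not without any 1 array other than molybdenum replicate A. As lists, the cycle (median 0.47, adjusted p = 0.0585), ATP synthase (median 0.58, adjusted p = 0.0585), nitrogen assimilation (median 0.44, adjusted p = 0.0635) and ribosomal proteins (median 0.17, adjusted p = 0.133) were not called. Without tungsten replicate C the first 3 were (adjusted p = 0.0279, 0.0192 and 0.0279), the cycle also without tungsten replicate B (adjusted p = 0.0430), and ribosomal proteins without molybdenum replicate A (adjusted p = 0.00347) or C (adjusted p = 0.0341).

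The 10 probe sets with the smallest p were all higher with tungsten, by 0.82 to 3.40, and none passed (adjusted p = 0.141 to 0.215). None has a gene symbol in the annotation used here. The largest, probe set 4217, read 10.47 ± 0.09 (n = 3) against 7.07 ± 0.78 (n = 3), and probe set 2369 9.17 ± 0.41 against 6.15 ± 0.68. Groups did not overlap for 837 probe sets (15.6%, where chance gives 10%).

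**Figure D2:**
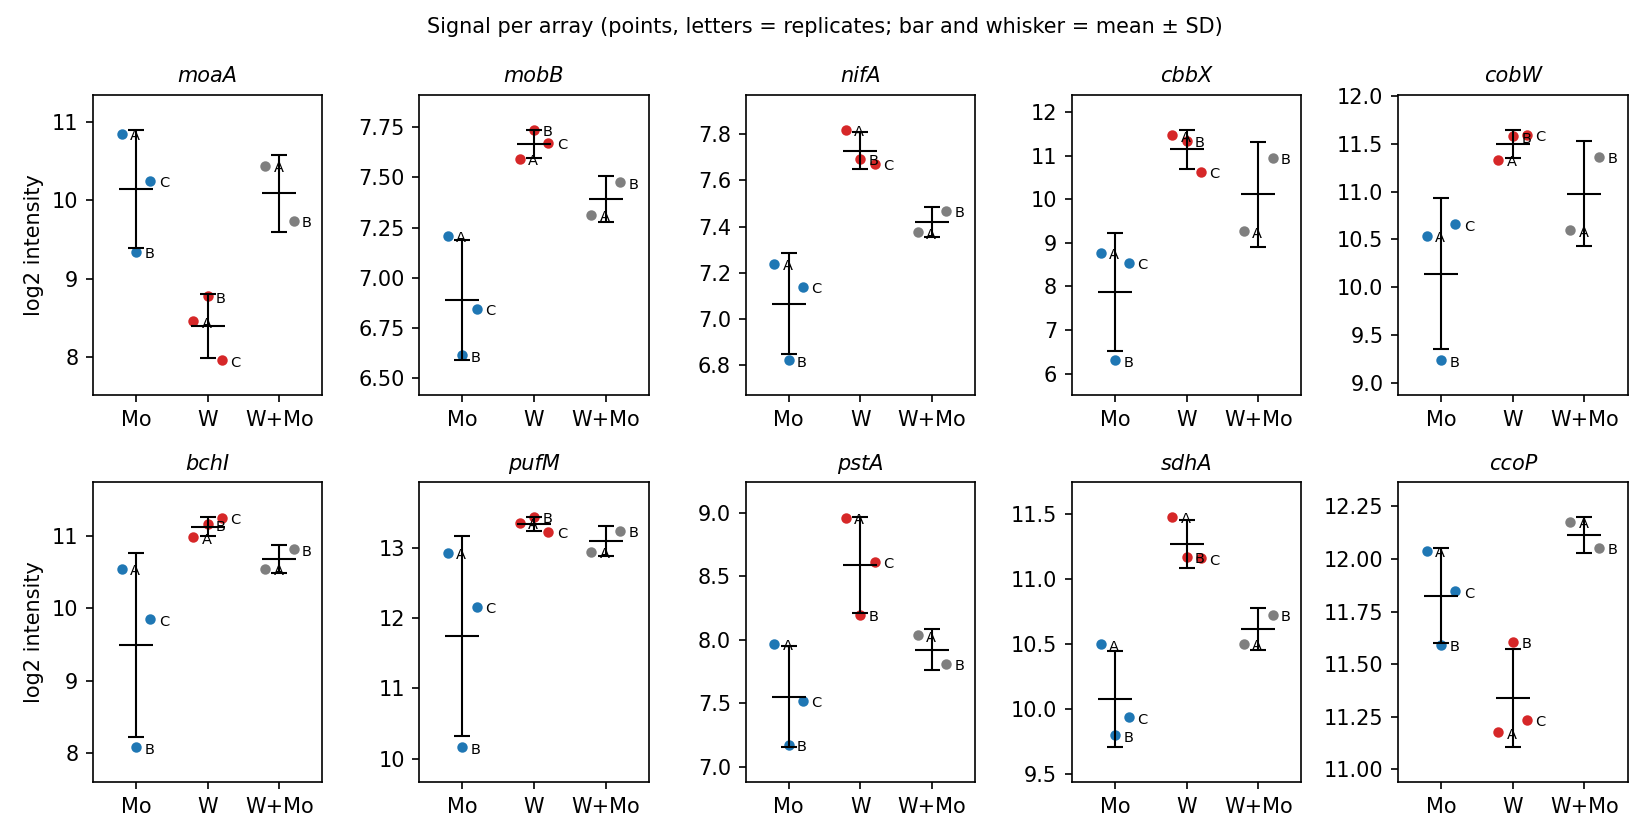
Log2 intensity on each array for 10 genes (Mo, molybdenum; W, tungsten in place of molybdenum; W+Mo, both metals); points are arrays, letters replicates, and the bar and whiskers the mean ± SD of 3, 3 and 2 arrays. Where a symbol has several probe sets the one with the smallest p for W against Mo is drawn. For moaA (3999 drawn) and sdhA (1875 drawn) these belong to different gene identifiers. The moaA probe set not drawn, 1103, read 6.92, 10.83 and 7.16 in Mo A, B and C and 7.39, 7.38 and 6.83 in W. In the panels moaA is lower in W (8.39 ± 0.41) than in the other groups, and cbbX is highest in W (11.15 ± 0.45).

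The comparison of tungsten plus molybdenum with molybdenum asks what tungsten does while molybdenum is present. With both metals cbbX stood at 10.11 ± 1.20 (n = 2), a log2 difference of 2.24 (SE 0.81) from molybdenum alone, but its arrays were far apart, with intensities of 614 and 1984. The difference was 3.08 without replicate A of these and 1.39 without B, and 1.45 without molybdenum replicate B. It did not pass over its list of 2 (adjusted p = 0.0559), but did without molybdenum replicate A (0.0408) or B (0.0331) or tungsten plus molybdenum replicate A (0.0355). moaA was close to its level with molybdenum: probe set 3999 read 10.09 ± 0.50 (n = 2) against 10.15 ± 0.76 (n = 3). All 11 probe sets of the photosynthetic complexes (median 1.13), all 26 of pigment synthesis (median 0.84) and all 11 of cobalamin synthesis (median 0.79) were higher. limma called 0 probe sets (lowest adjusted p = 0.636), and 162 had an unadjusted p under 0.05, where 268 would be expected by chance. That count was 1543 without molybdenum replicate A and 1739 with array weights, but 24 with only the 2 groups and 32 with the replicate block. limma called 2 without molybdenum replicate A, both without a symbol and lower. It called 0 under the other settings that left at least 2 arrays per group.

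Of the molybdenum genes, mobB differed by 0.50 (SE 0.19), modA by 0.89 (SE 0.48), mobA by 0.32 (SE 0.28) and moaA probe set 1103, of another gene identifier, by -1.18 (SE 1.08). The last turned to 0.08 without molybdenum replicate B, where it read 10.83 against 6.92 and 7.16. Over the list alone 0 of 8 passed, and 2 without molybdenum replicate A, mobB and modA. The differences of dorR (0.19, SE 0.22), dorS (0.02, SE 0.18), xdhA (0.04, SE 0.34) and xdhC (-0.02, SE 0.28) were smaller than or near their errors, and 0 of 4 passed over the list alone, while dorR and xdhA turned negative with quantile normalization, and dorS and xdhA with median centring. In the nif list, where 0 of 11 passed, nifA differed by 0.36 (SE 0.16), nifN by -0.32 (SE 0.15), nifK by -0.27 (SE 0.18) and nifD by -0.25 (SE 0.17). The nif list, lower in 10 of 11 members, was not called (camera, adjusted p = 0.0951), but was without molybdenum replicate A (adjusted p = 0.0337) or tungsten plus molybdenum replicate B (adjusted p = 0.0331).

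camera called 10 lists, all higher with both metals; 0 of their members passed over the list alone or over all genes. The photosynthetic complexes (adjusted p = 0.00113; adjusted p = 0.547 with an estimated correlation) included pucC (1.20, SE 0.60), pufM (1.35, SE 0.71), pufL (1.23, SE 0.73) and pufX (1.13, SE 0.70). They were not called without molybdenum replicate B, which lowered the median to 0.30 (adjusted p = 0.0854); without tungsten plus molybdenum replicate B it was 0.72. Pigment synthesis (adjusted p = 6.75e-08; adjusted p = 0.545 with an estimated correlation) included ppsR, for the repressor of photosynthesis genes (probe set 1156, 0.68, SE 0.25), bchE (0.56, SE 0.24) and bchO (0.68, SE 0.30). Its median was 0.28 without molybdenum replicate B and 1.26 without A. Over the list alone 5 probe sets passed without molybdenum replicate A: those of bchO and bchE and 1156, 1157 and 1158 of ppsR. Cobalamin synthesis (adjusted p = 0.000989; adjusted p = 0.545 with an estimated correlation) included cobM (1.07, SE 0.50), cobW (0.84, SE 0.45), cobF (0.79, SE 0.45) and cobO (0.36, SE 0.21), with a median of 0.33 without molybdenum replicate B and 0.49 without tungsten plus molybdenum replicate B.

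Flagella and chemotaxis (median 1.03; adjusted p = 1.13e-05; adjusted p = 0.545 with an estimated correlation) included flgL (0.71, SE 0.29), fliQ (0.99, SE 0.46), flgA (0.83, SE 0.39) and flhB (0.77, SE 0.35). The median was 0.41 without molybdenum replicate B. Ribosomal proteins (median 0.25; adjusted p = 0.000173; adjusted p = 0.580 with an estimated correlation) were not called without that array (median 0.08, adjusted p = 0.604), and their median was 0.43 without molybdenum replicate A. Among them rplB differed by 0.38 (SE 0.22), rplF by 0.45 (SE 0.27), rpsI by 0.37 (SE 0.21) and rpsU by -0.35 (SE 0.21). Adjusted p lay between 0.0430 and 0.0481 for the other 5 lists, each with an adjusted p = 0.545 with an estimated correlation. They were NADH dehydrogenase (nuoL 0.42, SE 0.24; nuoN 0.44, SE 0.26), terminal oxidases and cytochromes (ccmB 0.43, SE 0.26; cycA 0.44, SE 0.28) and nitrogen assimilation (gltB 0.54, SE 0.21; ntrX 0.51, SE 0.27). Another was the tricarboxylic acid cycle (fumC probe set 3072, 0.58, SE 0.25, and sucD 0.52, SE 0.21). The last was ATP synthase (atpD probe set 3233, 0.70, SE 0.33, and atpA probe set 3231, 0.64, SE 0.32). Each of the 5 lost its call without molybdenum replicate C (adjusted p = 0.136 to 0.210), and all except the terminal oxidases without molybdenum replicate B (adjusted p = 0.0696 to 0.0854). All except NADH dehydrogenase also lost it without molybdenum replicate A (adjusted p = 0.0571 to 0.0669) and without tungsten plus molybdenum replicate B (adjusted p = 0.0589 to 0.327). Without tungsten plus molybdenum replicate A NADH dehydrogenase (adjusted p = 0.0900) and nitrogen assimilation (adjusted p = 0.0708) were not called, and without tungsten replicate A ATP synthase was not (adjusted p = 0.0512). Members over the list alone passed without molybdenum replicate A in the tricarboxylic acid cycle (5), ATP synthase (2), NADH dehydrogenase (1) and nitrogen assimilation (1).

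Of the 10 probe sets with the smallest p, all higher by 0.53 to 2.06 and none past the test (adjusted p = 0.636), 2 have a symbol. rfbC, of the dTDP-rhamnose pathway, read 10.15 ± 0.04 (n = 2) against 9.63 ± 0.23 (n = 3), and metG, for methionyl-tRNA synthetase, 8.78 ± 0.23 against 7.97 ± 0.40. Groups did not overlap for 1029 probe sets (19.2%, where chance gives 20%).

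**Figure D3:**
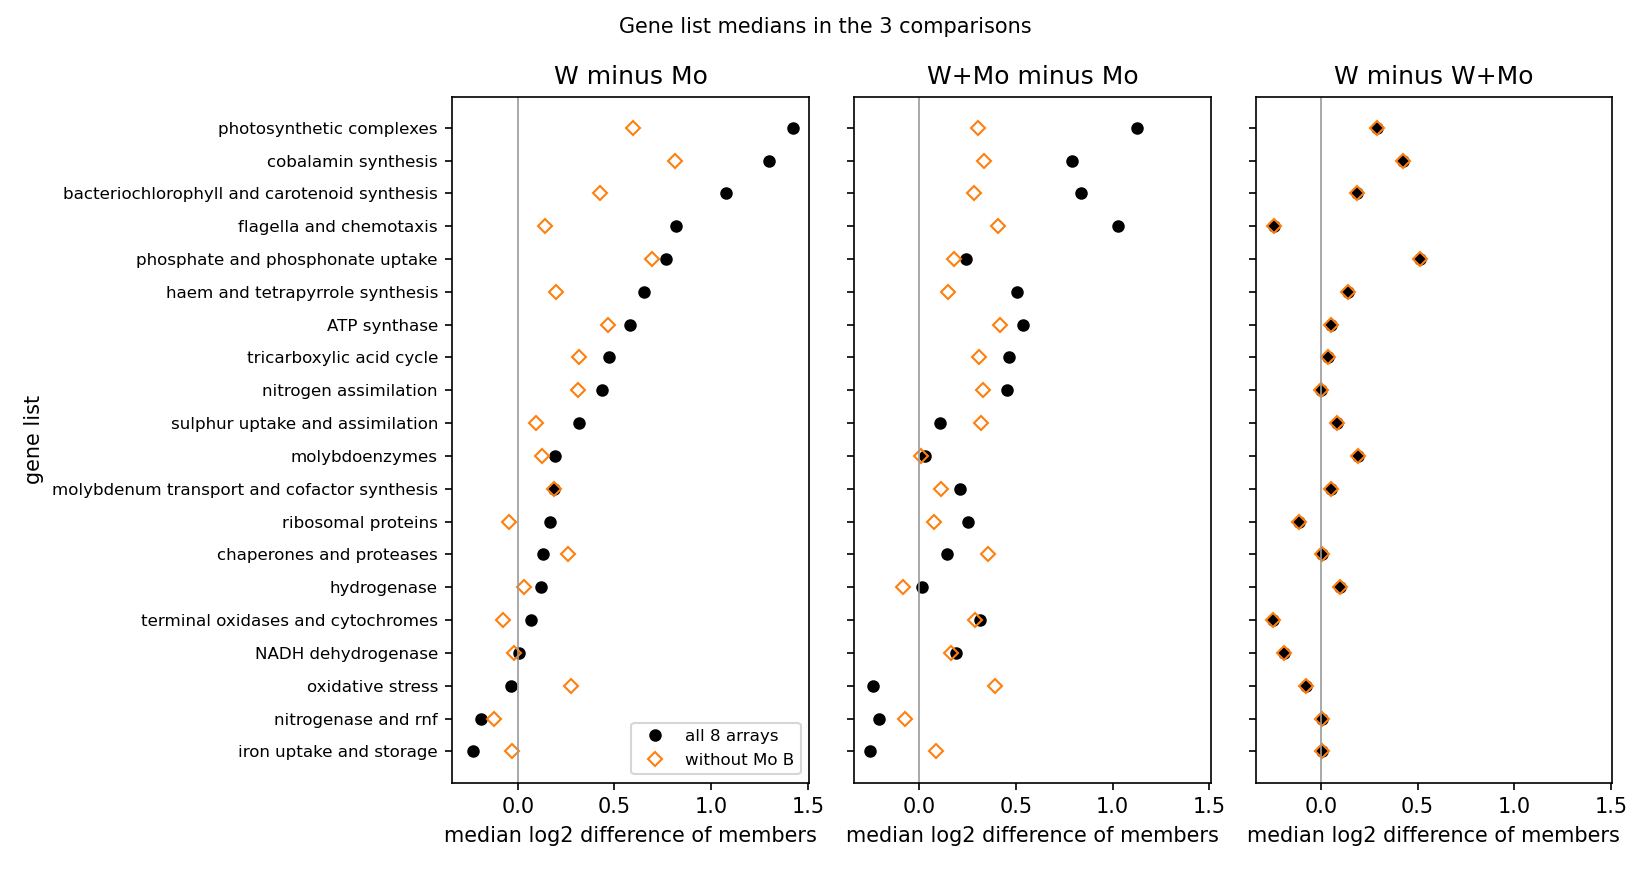
Median log2 difference over the probe sets of each of the 20 tested gene lists in the 3 comparisons (Mo, molybdenum; W, tungsten in place of molybdenum; W+Mo, both metals), with all 8 arrays (filled circles) and without molybdenum replicate B (open diamonds). Leaving out that array moves the photosynthetic complexes from 1.42 to 0.59 in W minus Mo and from 1.13 to 0.30 in W+Mo minus Mo; it enters no mean of W minus W+Mo.

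The comparison of tungsten in place of molybdenum with tungsten plus molybdenum asks what the lack of molybdenum does while tungsten is present. It is the direct test of whether the other comparisons differ. Genes for the cbb3 terminal oxidase, which has a high affinity for oxygen, were lower with tungsten alone than with both metals. ccoP read 11.34 ± 0.23 (n = 3) against 12.11 ± 0.09 (n = 2), and 11.83 ± 0.22 (n = 3) with molybdenum alone. ccoO read 11.73 ± 0.30 against 12.49 ± 0.03, and 12.13 ± 0.30 with molybdenum alone. In the same comparison moaA probe set 3999 was lower with tungsten alone, with a log2 difference of -1.70 (SE 0.47). The phosphate transporter genes pstC (0.77, SE 0.38), pstA (0.67, SE 0.30) and pstB (0.51, SE 0.29) were higher. limma called 0 of 5352 probe sets (lowest adjusted p = 0.734), and 104 had an unadjusted p under 0.05, where 268 would be expected by chance. The spread is shared with the molybdenum arrays, so a count below chance does not show that the groups are alike. With only the 5 arrays of these groups limma called 7, and 454 had an unadjusted p under 0.05. With array weights it called 2, with 537 under 0.05, and without molybdenum replicate B 1, with 262. Other settings stayed under 268, for example 120 with quantile normalization and 76 with an intensity trend.

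camera called 4 lists. Terminal oxidases and cytochromes were lower (median -0.25; adjusted p = 0.00204; adjusted p = 0.464 with an estimated correlation), with 1 of 7 past the test over the list alone, ccoP (-0.78, SE 0.20), and 0 over all genes. The gene ccoN differed by -0.53 (SE 0.27) and cycA by -0.25 (SE 0.28). The list's call was lost without tungsten plus molybdenum replicate B (adjusted p = 0.0662), and its median was -0.16 without tungsten replicate C. ccoP no longer passed without either array with both metals or without tungsten replicate A or C, nor with an intensity trend, a 2-fold minimum or without the dimmest probe sets, and 2 members passed without molybdenum replicate A or C or tungsten replicate B. NADH dehydrogenase (median -0.19; adjusted p = 0.00241; adjusted p = 0.609 with an estimated correlation) was lower in all 9 members, among them nuoK (-0.25, SE 0.18), nuoE (-0.20, SE 0.17), nuoC (-0.15, SE 0.14) and nuoI (-0.24, SE 0.22). Ribosomal proteins (median -0.12; adjusted p = 0.00125; adjusted p = 0.896 with an estimated correlation) were lower in 42 of 45, with rpmB at -0.39 (SE 0.22), rpsP at -0.41 (SE 0.36), rplS at -0.30 (SE 0.23) and rpmC at -0.22 (SE 0.17). Without tungsten plus molybdenum replicate A neither NADH dehydrogenase (adjusted p = 0.0831) nor ribosomal proteins (median -0.06, adjusted p = 0.453) were called; without replicate B their medians were -0.29 and -0.19. Phosphate uptake was higher in all 5 members (median 0.51; adjusted p = 0.000555; adjusted p = 0.464 with an estimated correlation), with phoU at 0.42 (SE 0.31). Its median was 0.23 without tungsten replicate A. Over the list alone 0 members passed in these 3 lists, as over all genes.

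Photosynthesis lists were not called here: the median was 0.29 for the complexes (adjusted p = 0.165) and 0.19 for pigment synthesis (adjusted p = 0.116), with 0 of 11 and 0 of 26 past the test over the list alone. Both were called without molybdenum replicate B (adjusted p = 1.89e-05 and 0.00017), which enters only the spread, and pigment synthesis also without tungsten plus molybdenum replicate B (adjusted p = 0.0471). Cobalamin synthesis, higher in 7 of 11 (median 0.42), was not called (adjusted p = 0.0551). It was without molybdenum replicate B (adjusted p = 0.00305), tungsten replicate A (0.0172) or C (0.0444) or tungsten plus molybdenum replicate B (0.0112). Its median was 0.07 without tungsten plus molybdenum replicate A and 0.73 without B. Flagella and chemotaxis, lower in 18 of 23 (median -0.24, adjusted p = 0.116), were called without molybdenum replicate B (0.0226), tungsten replicate B (0.000225) or tungsten plus molybdenum replicate A (0.000107). Their median was -0.56 without tungsten plus molybdenum replicate A, and without B the direction turned, with 15 of 23 higher (median 0.10). Differences were 0.36 (SE 0.60) for pucC, 0.40 (SE 0.70) for pufX, 0.39 (SE 0.73) for pufL and 0.31 (SE 0.59) for pufA probe set 1127. In pigment synthesis they were 0.47 (SE 0.30) for bchO, 0.25 (SE 0.24) for bchE, 0.49 (SE 0.58) for tspO and 0.45 (SE 0.57) for ppaA. Among the molybdenum genes 0 of 8 passed over the list alone, with mobB at 0.27 (SE 0.19), mobA at 0.07 (SE 0.28) and moaD at -0.17 (SE 0.41). The gene moaA did pass without molybdenum replicate A or B. With median centring, without the dimmest probe sets, with only the groups compared and with array weights 1 member of the list, lower, passed as well. The list was not called (camera, adjusted p = 0.815, downward); its median was 0.05 and its mean -0.17. In the molybdoenzyme list 0 of 4 passed. The difference was -0.52 (SE 0.22) for dorR, which did pass without molybdenum replicate B, and 0.37 (SE 0.18) for dorS. It was 0.37 (SE 0.34) for xdhA and 0.01 (SE 0.28) for xdhC, the last negative with quantile normalization or median centring. Among nif genes 0 of 11 passed, with nifA at 0.31 (SE 0.16), nifW at 0.09 (SE 0.12), nifS at -0.09 (SE 0.15) and nifX at -0.07 (SE 0.12).

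The remaining lists were not called in any comparison with the 8 arrays. For tungsten against molybdenum the median was 0.66 for haem synthesis (adjusted p = 0.111), 0.12 for hydrogenase (adjusted p = 0.402), 0.13 for chaperones and proteases (adjusted p = 0.402) and 0.32 for sulphur uptake (adjusted p = 0.437). It was -0.04 for oxidative stress (adjusted p = 0.934) and -0.23 for iron uptake (adjusted p = 0.817), whose means, too, were negative. Chaperones and proteases were called in tungsten plus molybdenum against molybdenum without molybdenum replicate B (adjusted p = 0.0172). In that array clpB, for a disaggregating chaperone, chosen after its values were seen, had an intensity of 2752 against 168 and 107 in replicates A and C. Among the lists too small to test, sufB of iron-sulphur cluster assembly differed by -0.68 (SE 0.59) between tungsten and molybdenum, and phaC of polyhydroxyalkanoate storage by 0.41 (SE 0.36). In other metal transport mgtE differed by 0.05 (SE 0.13), while cbiQ passed over that list of 2 (adjusted p = 0.0112).

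Of the 10 probe sets with the smallest p none passed (adjusted p = 0.734 to 1) and none has a symbol; 7 were higher and 3 lower. Probe set 2266 read 11.27 ± 0.05 (n = 3) with tungsten alone and 7.35 ± 0.28 (n = 2) with both metals, and in molybdenum replicates A, B and C 7.02, 10.12 and 7.43. Probe set 3995 read 9.90 ± 0.57 (n = 3) against 11.68 ± 0.31 (n = 2). Groups did not overlap for 1149 probe sets (21.5%, where chance gives 20%).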

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

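The tests without both replicates A of the groups with molybdenum, and with 1 value per gene, were chosen only after the results were seen; the other settings were planned. The number of arrays limits the precision. Among values for named genes under alternative settings, 2777 kept direction and side of the threshold, 70 passed the threshold in addition and 39 reversed. No named gene had passed over all genes, so no gene call could be lost. Leaving out an array of the group not compared also leaves a log2 difference unchanged. The 2777 therefore do not show that the gene results are stable. For called lists, 204 values kept both and 81 lost the call. For the 41 lists that were not called in a comparison, 29 of 615 values under alternative settings gained the call. The labels state nothing shared by arrays with the same letter. Deviations from the group means of molybdenum and tungsten arrays with the same letter correlated across probe sets at -0.21, -0.13 and 0.16. With the arrays with both metals, whose 2 deviations mirror each other, they correlated at 0.34 and 0.22 for molybdenum A and B and at -0.07 and 0.15 for tungsten A and B. As the labels name nothing shared, the letters were not used as pairs. The correlations, of mixed sign, do not exclude shared handling. With the replicate block limma called 0 probe sets in each comparison, with 507, 32 and 115 at an unadjusted p under 0.05.

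Probe sets called in tungsten against molybdenum, 0 with the 8 arrays, were 1 with an intensity trend, 1379 with array weights, 19 without both replicates A and 0 to 395 leaving out 1 array at a time. In tungsten plus molybdenum against molybdenum they were 0 to 2 leaving out 1 array. In tungsten against tungsten plus molybdenum they were 7 with only the 2 groups, 2 with array weights and 0 to 1 leaving out 1 array. Lists called numbered 0 in each comparison with an estimated correlation and 0 with fry. In tungsten against molybdenum (5) there were 8 with median centring and 4 to 8 leaving out 1 array. In tungsten plus molybdenum against molybdenum (10) there were 5 with the replicate block, 5 with quantile normalization and 5 to 10 leaving out 1 array. In tungsten against tungsten plus molybdenum (4) there were 3 to 8 leaving out 1 array. Where a group was left with 1 array, that array is assumed to vary like the other groups. The cause was not tested for any of these changes.

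Members past the test over the list alone also moved with settings other than leaving out 1 array. In tungsten against molybdenum, cobalamin synthesis (6) had 1 with quantile normalization, 0 with the replicate block and 1 without both replicates A. Phosphate uptake (3) had 0 with quantile normalization or only the 2 groups, and 1 without both replicates A. The tricarboxylic acid cycle (5) had 2 with quantile normalization, 3 with an intensity trend or the replicate block and 1 with a 2-fold minimum. The nif list (1) had 0 with quantile normalization, median centring, only the 2 groups, an intensity trend, a 2-fold minimum, the replicate block or without both replicates A, and 6 with array weights. Haem synthesis (2) had 1 with median centring, only the 2 groups or an intensity trend, 0 with a 2-fold minimum or the replicate block and 4 with array weights. Iron uptake (1) had 0 with only the 2 groups, an intensity trend, a 2-fold minimum or the replicate block. The molybdenum genes (2) had 1 with a 2-fold minimum, 4 with array weights and 3 without both replicates A. With array weights the photosynthetic complexes (0) had 6 and pigment synthesis (0) 22. In tungsten against tungsten plus molybdenum, terminal oxidases (1) had 0 without the dimmest probe sets, with an intensity trend, a 2-fold minimum or the replicate block and without both replicates A, 2 with median centring, only the 2 groups or an offset of 16 and 3 with array weights. Molybdoenzymes (0) had 1 with only the 2 groups or array weights, the tricarboxylic acid cycle (0) 1 and 2 with these, ATP synthase (0) 1 with the replicate block, and the Calvin cycle (0) and other metal transport (0) 1 each with array weights.

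Reversed log2 differences in tungsten against molybdenum were -0.0530 for mobA and 0.157 for xdhC with array weights, and 0.136 for xdhC without both replicates A. Leaving out 1 array gave -0.158 to 0.235 for xdhC and -0.0220 to 0.435 for phoU. In tungsten plus molybdenum against molybdenum, quantile normalization gave -0.0442 for dorR and -0.179 for xdhA, median centring -0.0242 for dorS and -0.00812 for xdhA, and array weights -0.00373 for dorR. The replicate block gave -0.0253 for dorS, -0.0941 for xdhA and -0.143 for atpD probe set 4901, and leaving out both replicates A -0.0874 for xdhA. Leaving out 1 array gave -1.88 to 0.0804 for moaA probe set 1103, -0.00424 to 0.297 for dorR, -0.106 to 0.153 for dorS, -0.355 to 0.434 for xdhA, -0.190 to 0.147 for xdhC and -0.106 to 0.485 for atpD probe set 4901. In tungsten against tungsten plus molybdenum, the replicate block gave 0.143 for moaD and -0.124 for mobA, array weights -0.106 for mobA, quantile normalization -0.0177 and median centring -0.0134 for xdhC, and leaving out both replicates A -0.125 for pucC. Leaving out 1 array gave -0.391 to 0.101 for moaD, -0.159 to 0.211 for mobA, -0.0237 to 0.766 for xdhA, -0.156 to 0.257 for xdhC, -0.181 to 0.00839 for nifS and -0.125 to 0.839 for pucC. The cause was not tested.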

Other observations

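The tests on molybdenum replicate B, on replicates with the same letter and on the number of genes over other splits were chosen only after the results were seen; so were the spread of the 1 RNA test and its version with molybdenum replicate B, while its version with replicate C and the test on the number of lists over other splits were set beforehand.

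The gene appA, for the light- and redox-sensing antirepressor of photosynthesis genes, is in no list and was chosen after its values were seen. Its 5 probe sets were higher with tungsten than with molybdenum by 0.85 to 1.16, though none passed limma's test over all genes (adjusted p = 0.307 to 0.329). Probe set 2475 of appA read 8.64 ± 0.07 (n = 3) with tungsten, 7.48 ± 0.57 (n = 3) with molybdenum and 8.18 ± 0.11 (n = 2) with both metals. The 5 probe sets of fnrL, for the oxygen-responsive activator, differed by 0.16 to 0.25. The gene infA, for a translation initiation factor, also chosen after its values were seen, read 10.80 ± 0.04 (n = 3) with tungsten and 11.74 ± 0.66 (n = 3) with molybdenum, where its intensity was 5522 in replicate B and 2229 and 3235 in A and C.

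Molybdenum replicate B stands apart from the other 7 arrays. A monotone rescaling of its signal would keep the ranks, but its highest rank correlation with another array was 0.881, below the lowest among the other pairs, 0.944. Random noise of single probe sets is argued against by probe sets of 1 gene, which deviated together: over 10 genes the intraclass correlation was 0.778 (1-sided permutation p = 1e-04, the smallest the permutations can give). A label swap within the series would leave the array as far from its new group, so a swap alone would not set it apart. Its highest correlation with an array of another group was 0.861, below the lowest among pairs of the other 7 arrays, 0.937. Whether labels were also swapped cannot be told from this, as the array is far from every group. A swap would need a partner out of place, and tungsten plus molybdenum replicate A was closer to molybdenum replicate A (r = 0.997) than to the other array of its group (r = 0.983). A different state of the culture, an array from outside the series or a handling difference remain open, and no biological explanation was tested.

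Molybdenum replicate A and tungsten plus molybdenum replicate A resemble each other more than any replicates of 1 group. If 1 RNA had been measured on both arrays, their difference would be unrelated to that between tungsten plus molybdenum replicate B and molybdenum replicate C. The correlation across probe sets, which are not independent replicates, was 0.12, over the bound of 0.1 by less than its spread (SD 0.0273 over 1000 resamplings of the probe sets), so 1 RNA may still be the source; with molybdenum replicate B in place of C it was 0.03. Shared handling of arrays with the same letter stays open as well: for molybdenum and tungsten arrays the mean correlation of deviations with the same letter minus that with different letters was -0.0877, within the SD of the latter, 0.172; no biological explanation was tested.

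The 6 arrays with either metal alone allow 10 splits into 3 and 3, too few for a share under 0.05. limma called 0 probe sets in the real split and at most 0 in the others; with a real count of 0 all 10 had to give as many, so this comparison says nothing about chance. camera called 5 lists in the real split and at most 8 in another, and 6 of 10 splits gave as many. The split with 8 lists sets molybdenum replicate A with tungsten replicates A and B against the rest, with 767 probe sets at an unadjusted p under 0.05 against 601 in the real split.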
